A study of Homo sapiens with 6 samples.

How the data were processed

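RNA was measured by sequencing of polyA-selected transcripts in 6 libraries, 3 from parental MDA-MB-231 cells and 3 from the glutamine-independent derivative MDA-MB-231GlnIND. Per the labels' protocols, RNA was isolated with a column kit from cells frozen on the plate, and libraries were made with the Kapa mRNA HyperPrep kit by oligo-dT enrichment, random-primed first-strand synthesis, adaptor ligation and PCR. The authors deposited raw read counts per gene symbol, 1 table per library and 1 matrix of all libraries. Per the submitters' processing notes, the tools were FastQC, STAR, featureCounts and DESeq, and the genome build was hg19. Their versions, the gene annotation, the strand setting and the treatment of multiply mapped reads were not given in the sources used here. Overlapping, antisense and near-identical genes may therefore share counts or lose them. VARS1, a synthetase that cells generally need, was at most at 0.184 CPM in any library, so a value near 0 is not by itself evidence of low expression.

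The deposited matrix and the per-library tables held the same values, but the names of replicates 1 and 3 were exchanged within each group. The matrix column named parental 1 was equal to the table of parental 3 at 100% of genes, and the same held for GlnIND. The exchange leaves the groups untouched. Replicate numbers here follow the per-library tables. Each table had 28265 gene rows, of which 8283 were at 0 in every library. In 1 row the gene name had turned into a date, and that row had no counts.

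Total counts ranged from 18256219 to 24594248 per library. Low counts were mostly even. Between 981 and 1079 genes per library had exactly 2 counts, against 513 to 590 genes with exactly 1 count, and 60.6% to 65.0% of the genes under 20 counts had an even count. Above 1000 counts the share was 49.8% to 51.2%. Such a pattern arises when both ends of a read pair are counted, up to 2 counts for 1 molecule. Detection floors were therefore set at 3 read pairs, or 6 counts, and counting intervals were computed on halved counts. The floor was 0.244 to 0.329 CPM, which is read counts scaled to library size, in a single library. A fold against a group at 0 was computed against 6 counts over the group. Groups with 1 to 6 counts were given a ratio with an exact 95% Clopper-Pearson interval. Floors and intervals cover counting error only, since PCR copies were not removed by molecular identifiers.

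The counts were tested as deposited with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided), with TMM factors and the default filterByExpr filter (minimum count of 10, minimum total of 15). The design held the group alone. Of the genes in the table, 13949 were tested, which held 99.94% of all counts, and 14316 were not. The common biological coefficient of variation was 9.8%. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. CPM values are TMM-normalised and given as mean ± SD with n = 3 per group, and log2 fold changes are GlnIND over parental with their standard error (SE), computed from the F statistic. A permutation test of 3 libraries against 3 cannot give a p under 0.1, so p-values come from models fitted over all genes.

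The comparison, its test, the alternatives and 25 gene lists were fixed before the data were examined. Lists with at least 5 tested genes, 22 in all, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists. The test was repeated with an estimated correlation per list and with fry, whose directional p asks whether a list's genes move one way and does not compare them with other genes. With an estimated correlation camera uses the residual degrees of freedom of the 6 libraries, far fewer than at the preset value. Its p-values are then larger even at an equal correlation. All list members were found among the gene symbols, some of them under an older symbol. The rule for the 58 named genes was also fixed beforehand. It took PSAT1, PHGDH, PSPH, GLUL, ASNS, GOT1, GOT2, GPT2 and ATF4. It added the 5 highest and 5 lowest log2 fold changes among called genes with a mean CPM of at least 5 and no overlap between groups. From each list of pathway genes it took the 2 called members with the largest change and a mean CPM of at least 1. Some genes that the rule or the lists cover are not reported here.

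The fixed alternatives were RLE and upper-quartile factors, no filter on low counts, a CPM of at least 1 in 3 libraries, each library left out in turn, the replicate number as a block, DESeq2 1.42.0, limma-voom, robust dispersion, an adjusted p under 0.01, glmTreat against a log2 fold change of 1, and the matrix in place of the tables. Alternatives added after the data had been seen were library totals without composition factors, removal of a GC trend, and removal of the shift of neighbouring genes. The removed neighbour shift was treated as known, so SE and p-values after its removal leave out its own error. The GC trend was a loess curve (span 0.5) of each library's log2 CPM deviation on the GC percent of the gene's longest GENCODE release 29 transcript, which was found for 13335 tested genes (95.6%). Neighbouring genes were ordered by the RefSeq gene table of GRCh38.p14. That build differs from the build of the counts, so it was used for gene order and overlap only and no coordinates are given. Genes with a mean CPM of at least 2 were placed in windows of 40 consecutive genes, and window medians were compared with those of 1000 shuffled gene orders, with log2 fold changes limited to 2 in size.

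The scripts were tested on counts simulated for the GlnIND and parental comparison, with 13743 genes tested. The test recovered 56.7% of 67 genes changed 1.5-fold, 88.1% of 67 genes changed 2-fold and 92.4% of 66 genes changed 4-fold, and it called 8 unchanged genes. Camera called 2 lists, 1 of them the list that had been shifted and the other a list that had not. Simulated genes varied independently of each other, so the simulation does not test list calls where genes are correlated. The notes in an unnamed column of the matrix were not used here.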

Results

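Gene expression was profiled by polyA RNA sequencing in MDA-MB-231, an established human triple-negative breast cancer cell line, and in MDA-MB-231GlnIND, a derivative able to grow without glutamine. Parental cells were kept in glutamine-replete RPMI medium with fetal bovine serum. GlnIND cells had been cultured for more than 6 weeks in glutamine-free medium with dialysed serum, so the cell population, the glutamine supply and the type of serum differed together. Each of the 2 groups had 3 libraries. Total counts per library ranged from 18256219 to 21741371 in the parental group and from 21276815 to 24594248 in the GlnIND group, and 16500 to 17642 genes had at least 1 count. The labels do not say whether the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

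The comparison of GlnIND with parental cells asked which transcripts accompany adaptation to long-term glutamine withdrawal. In GlnIND cells PHGDH, the first enzyme of serine synthesis from a glycolytic intermediate, was 4.02-fold higher, and GLUL, the enzyme that makes glutamine from glutamate and ammonia, was 3.65-fold higher. PSAT1, the aminotransferase of the serine pathway, did not pass the test. Cytokine and NF-kB target genes, endoplasmic reticulum chaperones and genes of cholesterol synthesis, fatty acid synthesis and glycolysis were lower as groups. These 5 list calls used a preset correlation of 0.01, and with an estimated correlation the adjusted p values lay between 0.165 and 0.617. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 7853 of 13949 tested genes (56.3%) changed, 3965 of them higher and 3888 lower in GlnIND cells. Among the called genes 2107 differed by more than 2-fold, 1373 of them higher and 734 lower. When the change itself was tested against a log2 fold change of 1, 1006 genes passed, 656 higher and 350 lower. The CPM ranges of the groups did not overlap at 9068 genes (65%), against 10% by chance. The split between directions rested on the scaling. The median log2 fold change of all genes was 0.03 with TMM factors, 0.12 with upper-quartile factors and 0.18 with library totals alone, and the counts of higher and lower genes were then 4749 and 3204, and 5356 and 2810.

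Of the genes of serine synthesis, PHGDH rose from 15.4 ± 1.57 CPM in parental cells to 61.7 ± 0.648 CPM in GlnIND cells (SD, n = 3 each), a log2 fold change of 2.01 (SE 0.094, edgeR adjusted p = 2.95e-07). PSAT1 was at 201 ± 18.8 CPM in parental and 231 ± 18.4 CPM in GlnIND cells (SD, n = 3 each), a log2 fold change of 0.20 (SE 0.086, edgeR adjusted p = 0.0718). All 3 GlnIND libraries (219 to 252.5 CPM) lay above all 3 parental libraries (179.7 to 213.3 CPM) for PSAT1, as they did for PHGDH and GLUL. PSPH, which releases serine in the last step, fell by 0.82 on the log2 scale (SE 0.1, edgeR adjusted p = 0.000103). PSAT1 passed the threshold under 5 alternatives. Its log2 fold change was 0.11 without parental 1 (adjusted p = 0.0457), 0.29 with upper-quartile factors (0.0182), 0.35 with library totals alone (0.00812), 0.27 with the GC trend removed (0.0285) and 0.35 with the shift of neighbouring genes removed (0.00807). The last of these p-values leaves out the error of the removed shift, and the SE stayed at 0.086. Relative to the median of all genes, the PSAT1 log2 fold change was 0.17 with TMM, upper-quartile and total scaling alike. Without GlnIND 1 the PSAT1 log2 fold change itself was 0.12 (edgeR adjusted p = 0.315).

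GLUL rose from 35.8 ± 0.946 to 131 ± 2.72 CPM (SD, n = 3 each), a log2 fold change of 1.87 (SE 0.067, edgeR adjusted p = 6.29e-08). The aminotransferase genes GOT2 and GPT2, which encode mitochondrial enzymes, rose by 0.32 and 0.54 on the log2 scale (SE 0.073 and 0.1). GOT1, the cytosolic aspartate aminotransferase, was at 74.9 ± 7.86 and 68.3 ± 4.47 CPM (SD, n = 3 each), with an edgeR adjusted p of 0.242. ASNS, which uses glutamine to make asparagine, was listed at 0.903 ± 0.48 and 2.09 ± 0.262 CPM (SD, n = 3 each) and rose by 1.22 on the log2 scale (edgeR adjusted p = 0.016). A further row, CZ1P-ASNS, spans 99% of this gene and had 45 parental and 58 GlnIND counts beside 51 and 152 for ASNS. Reads that match both rows may have been left uncounted, so these values do not give the expression level of ASNS. ATF4, the transcription factor of the amino acid response, fell by 0.35 on the log2 scale (SE 0.072, edgeR adjusted p = 0.00241). The ASNS call was lost without GlnIND 2 (adjusted p = 0.0605) or GlnIND 3 (0.0563), and GOT1 passed without parental 1 (-0.21, 0.00341) and with the GC trend removed (-0.25, 0.0112). The 40 neighbouring genes around GPT2 had a median log2 fold change of 0.75, and with the neighbour shift removed GPT2 turned to -0.23 (adjusted p = 0.0804) and GOT2 stood at 0.07 (0.456). ATF4 stood at -0.53 with the GC trend removed and at -0.20 with library totals alone.

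**Figure D1:**
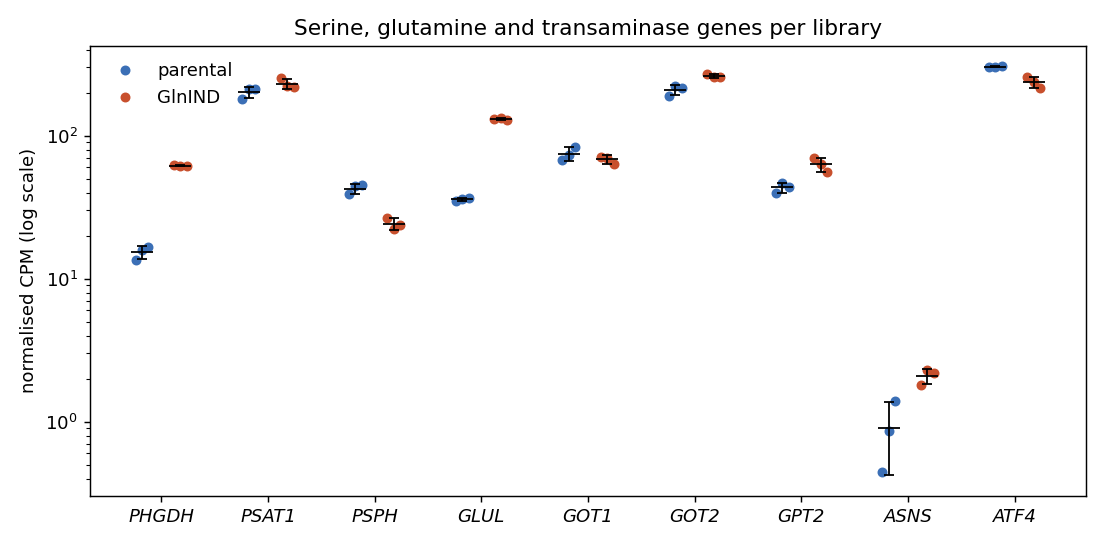
TMM-normalised CPM on a log axis for 9 genes of serine, glutamine and aminotransferase metabolism, 1 point per library, with group mean and SD bars (n = 3 per group). PHGDH, at 15.4 and 61.7 CPM, and GLUL, at 35.8 and 131 CPM, separate the groups widely. The PSAT1 libraries also do not overlap between groups but lie closer, around means of 201 and 231 CPM.

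The lists that hold these genes had members moving both ways. For all lists, counts adjusted over the list alone equalled those over all genes except where another count is given. Among 16 tested genes of serine, glycine and one-carbon metabolism, 6 rose, 6 fell and 4 were not called (camera adjusted p = 0.949). AMT, a subunit of the glycine cleavage system, rose by 1.85 on the log2 scale beside PHGDH. Of 11 transaminase genes 6 rose, 1 fell and 4 were not called (camera adjusted p = 0.257). KYAT1 rose by 1.02 on the log2 scale, and ABAT, which degrades the neurotransmitter GABA, had 4 counts in all parental libraries and 454 in GlnIND libraries, a ratio of 89.2 (95% interval 24.4 to 741). Without parental 1 or with the GC trend removed 2 transaminase genes fell, and with the neighbour shift removed 0 fell. Of 14 genes of glutamine synthesis and use, 4 rose, 6 fell and 4 were not called (camera adjusted p = 0.548), with GFPT2, which makes glucosamine phosphate from glutamine, falling by 1.29 on the log2 scale. Without GlnIND 2 or GlnIND 3, 2 of the 14 rose.

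The largest differences were in genes detected in 1 group and nearly undetected in the other. PGM5 (phosphoglucomutase-like protein) and HS6ST2 (a heparan sulfate sulfotransferase) had 0 counts in the parental libraries and were at least 290-fold and at least 123-fold higher in GlnIND cells, at 30.8 ± 4.16 and 12.9 ± 1.65 CPM (SD, n = 3). EPB41L3, a membrane skeleton protein, had 4 parental and 4638 GlnIND counts, a ratio of 911 (95% interval 252 to 7530). The ratio was 868 (155 to 34300) for the cancer-testis antigen MAGEA10 and 332 (91.7 to 2750) for AMPH, the endocytic protein amphiphysin. In the opposite direction CCBE1, a secreted factor of lymphatic development, and the KRAB domain gene KRBOX1 had 0 counts in GlnIND libraries and were at least 361-fold and at least 237-fold lower. MAGEC1, a further cancer-testis antigen, fell from 118 ± 4.37 CPM (SD, n = 3) to 4 counts in all GlnIND libraries, a ratio of 2130 (589 to 17600). The parental to GlnIND ratio was 1220 (218 to 48200) for ZNF300 and 1160 (208 to 46000) for PTPRN2. The edgeR adjusted p of these 10 genes was at most 1.21e-06. Over all tested genes, 77 had 0 to 6 counts in the parental group and at least 1 CPM in GlnIND cells, and 47 had the reverse pattern. The windows of neighbouring genes that hold HS6ST2, MAGEA10 and MAGEC1 on chromosome X had medians of -1.07, -0.82 and -1.01.

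Inflammatory cytokine and NF-kB target genes had the lowest median of the lists. Of 15 tested genes 12 fell, 1 rose and 2 were not called, the same counts as adjusted over the list alone, with a median log2 fold change of -2.18 (camera adjusted p = 1.49e-06, and adjusted p = 0.165 with an estimated correlation). CSF3 and CSF2, colony-stimulating factors for granulocytes and macrophages, fell from 10.4 ± 1.17 and 19.0 ± 5.75 CPM to 0.378 ± 0.182 and 0.73 ± 0.315 CPM (SD, n = 3 each). The neutrophil chemokine CXCL8 fell from 122 to 18 CPM, and the inhibitor NFKBIA fell by 1.65 on the log2 scale. PTGS2, a prostaglandin synthase, rose by 0.43, and IL6 and IL1B had log2 fold changes of -0.53 and -0.26 (edgeR adjusted p = 0.179 and 0.288).

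Endoplasmic reticulum chaperone genes fell together. Of 18 genes 14 fell, 2 rose and 2 were not called, also when adjusted over the list alone, with a median of -0.60 (camera adjusted p = 0.000794, and adjusted p = 0.412 with an estimated correlation). HSPA5, the abundant chaperone BiP, fell from 952 ± 39.3 to 375 ± 10.2 CPM and HYOU1, a large chaperone of the same family, from 588 ± 24.1 to 179 ± 4.68 CPM (SD, n = 3 each). The genes that rose were HERPUD1 and EDEM1, both of endoplasmic reticulum degradation, by 0.41 and 0.22 on the log2 scale. HYOU1 lies in a window with a median of -1.03, and with the neighbour shift removed its log2 fold change was -0.70. The 2 genes that rose numbered 1 without parental 2 or any of the 3 GlnIND libraries, and 0 with the neighbour shift removed.

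Genes of lipid synthesis were also lower. Of 25 cholesterol genes 14 fell (15 adjusted over the list alone), 2 rose and 9 were not called, with a median of -0.31 (camera adjusted p = 0.00312, and adjusted p = 0.412 with an estimated correlation). INSIG1, a sterol-responsive regulator, fell by 1.43 on the log2 scale, while TM7SF2, a sterol reductase, rose by 1.67. SQLE stood at 31.6 CPM in both groups. Of 11 fatty acid synthesis genes 7 fell, 0 rose and 4 were not called, also when adjusted over the list alone, with a median of -0.36 (camera adjusted p = 0.038, and adjusted p = 0.45 with an estimated correlation). SCD, the desaturase of stearate, fell from 521 ± 10.9 to 175 ± 3.47 CPM and ACSL3, an acyl-CoA synthetase, from 242 ± 29 to 122 ± 2.27 CPM (SD, n = 3 each). The fatty acid call was lost without parental 2 (adjusted p = 0.0595), GlnIND 1 (0.0508) or GlnIND 3 (0.0593), and 1 gene rose without parental 1 or GlnIND 3. With library totals alone the cholesterol median was -0.15 and the fatty acid median -0.21. With the neighbour shift removed the fatty acid median was -0.67 and TM7SF2 stood at 0.97.

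Of 19 glycolysis genes 10 fell, 1 rose and 8 were not called, also when adjusted over the list alone, with a median of -0.32 (camera adjusted p = 0.038, and adjusted p = 0.617 with an estimated correlation). TPI1 fell from 669 ± 65.1 to 353 ± 16.4 CPM (SD, n = 3 each), and PGK1, GAPDH and LDHA fell by 0.82, 0.69 and 0.67 on the log2 scale. The lactate exporter SLC16A3 fell from 130 ± 51.9 to 72.4 ± 1.12 CPM (SD, n = 3 each, edgeR adjusted p = 0.0169). Parental 1, at 69.93 CPM, lay below all GlnIND libraries (71.16 to 73.36 CPM), while parental 2 and 3 were at 157.1 and 162.4 CPM. The SLC16A3 call was lost without parental 2 (edgeR adjusted p = 0.056), GlnIND 1 (0.0542), GlnIND 2 (0.0597) or GlnIND 3 (0.0545). Its log2 fold change stood at -1.39 with the neighbour shift removed. The gene that rose was ALDOC, an aldolase, by 0.41 on the log2 scale. Without parental 1, 2 genes of the list rose, and 0 rose when any other library was left out or the GC trend was removed. The list's call was lost with upper-quartile factors (camera adjusted p = 0.0672), with library totals (0.104), without parental 2 (0.0576), GlnIND 1 (0.0508) or GlnIND 3 (0.0593), and with the neighbour shift removed (0.0824, with 6 genes lower). The median was -0.17 with library totals and -0.19 with the neighbour shift removed.

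Mitochondrial lists were mixed. In the tricarboxylic acid cycle list 4 of 22 genes rose, 10 fell and 8 were not called (camera adjusted p = 0.236). PC, which feeds pyruvate into the cycle, rose by 1.11 on the log2 scale, and DLAT, a subunit of pyruvate dehydrogenase, fell by 1.33. In the oxidative phosphorylation list 5 of 28 genes rose, 8 fell and 15 were not called (camera adjusted p = 0.72). NDUFV1 rose by 1.04 and NDUFA1 fell by 0.80 on the log2 scale, both subunits of complex I. Without GlnIND 1 or GlnIND 2, 3 genes of this list rose. Neighbours shifted with several of these genes. The window medians were 0.55 for PC and NDUFV1, -1.03 for DLAT and -1.07 for NDUFA1, and with that shift removed the log2 fold changes were 0.57, 0.50, -0.31 and 0.28 (adjusted p = 0.0619 for NDUFA1). The members of the cycle list that rose and fell were then 2 and 6, and 4 oxidative phosphorylation genes fell.

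Among 22 target genes of ATF4 in the amino acid response 6 rose, 6 fell and 10 were not called (camera adjusted p = 0.623). NUPR1, a stress-induced nuclear protein, rose from 1.29 ± 0.471 to 13.9 ± 2.11 CPM, and SLC7A11, the cystine-glutamate exchanger, fell from 134 ± 9.96 to 40.3 ± 0.729 CPM (SD, n = 3 each). Of 19 cytosolic aminoacyl-tRNA synthetase genes 2 rose, 10 fell and 7 were not called (camera adjusted p = 0.221). QARS1, for glutamine, rose by 0.60 on the log2 scale and NARS1, for asparagine, fell by 1.03, and with the neighbour shift removed they stood at 0.21 and -0.42. Without parental 1 or with the GC trend removed 4 synthetase genes rose. Among 22 amino acid transporters 10 rose (11 adjusted over the list alone), 6 fell and 6 were not called (camera adjusted p = 0.471), with SLC6A9, a glycine transporter, rising by 1.96 on the log2 scale. Of 21 nucleotide synthesis genes 3 rose, 11 fell and 7 were not called (camera adjusted p = 0.19). CTPS2, which uses glutamine to make CTP, rose by 0.98 on the log2 scale (0.64 with the neighbour shift removed), and IMPDH1, of guanine nucleotide synthesis, fell by 1.04. IMPDH1 lies in a window with a median of -0.74 and stood at -0.30 with that shift removed (adjusted p = 0.0696).

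In the NRF2 and glutathione list 5 of 18 genes rose, 7 fell and 6 were not called (camera adjusted p = 0.425), with AKR1C1, an aldo-keto reductase, rising by 1.98 on the log2 scale. The genes that rose numbered 3 without parental 2, 1 without GlnIND 1, 2 without GlnIND 2 or GlnIND 3 and 2 with the neighbour shift removed, and 11 fell without parental 1 or with the GC trend removed. Of 28 cell cycle genes 7 rose (8 adjusted over the list alone), 12 fell (13 adjusted over the list alone) and 9 were not called (camera adjusted p = 0.391). FOXM1, a mitotic transcription factor, and cyclin gene CCNE2 fell by 0.93 and 0.86 on the log2 scale, and by 0.48 and 0.34 with the neighbour shift removed. Without GlnIND 1, 2 or 3 the genes that rose numbered 4, 3 and 4, and with the neighbour shift removed 4. Of 12 hypoxia-induced genes 2 rose, 5 fell and 5 were not called (camera adjusted p = 0.268), including VEGFA, the endothelial growth factor, and BNIP3, a mitophagy receptor, which fell by 1.18 and 0.95 on the log2 scale. Among 21 lysosome and autophagy genes 9 rose, 8 fell and 4 were not called (camera adjusted p = 0.986). NPC1, which exports cholesterol from lysosomes, rose from 89.5 ± 6.39 to 247 ± 5.76 CPM (SD, n = 3 each), and TFEB, a transcription factor of lysosomal genes, rose by 1.90 on the log2 scale from 0.76 CPM. With the neighbour shift removed 5 genes of this list fell.

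Of 22 interferon-stimulated genes 8 rose, 3 fell and 11 were not called (camera adjusted p = 0.336). BST2, an antiviral membrane protein, fell from 73.9 ± 13.2 to 10.3 ± 0.294 CPM (SD, n = 3 each), and MX2 rose by 2.02 on the log2 scale from 0.407 CPM. Without GlnIND 3, 5 genes of the list rose. Among 15 mesenchymal genes 6 rose, 6 fell and 3 were not called (camera adjusted p = 0.699). TGFBI, an extracellular matrix protein, fell by 2.30 on the log2 scale from 77.3 CPM. SPARC, a collagen-binding protein, rose by 1.58 on that scale from 0.556 CPM, near the detection floor. Of 9 epithelial genes 2 rose, 5 fell and 2 were not called (camera adjusted p = 0.236). The adhesion molecule EPCAM fell from 14.3 ± 2.62 to 2.22 ± 0.366 CPM, and ESRP1, an epithelial splicing regulator, rose from 0.241 ± 0.11 to 3.36 ± 1.03 CPM (SD, n = 3 each).

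Few markers of other cell types had enough counts to be tested. All 3 tested fibroblast markers rose. COL1A1 went from 5.00 to 12.3 CPM, PDGFRB from 1.07 to 3.08 CPM and LUM from 0 counts to 2.35 CPM, and the other 4 were below 0.79 CPM in every library. None of the 3 tested blood cell markers was called, including CD68 at 178 and 177 CPM. Of the 2 tested endothelial markers PECAM1 rose from 2.41 to 4.34 CPM and KDR was not called. Of 5 luminal breast markers 1 rose, 2 fell and 2 were not called (camera adjusted p = 0.699), with ERBB3 rising from 5.33 to 11 CPM and FOXA1 falling from 5.82 to 3.22 CPM.

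**Figure D2:**
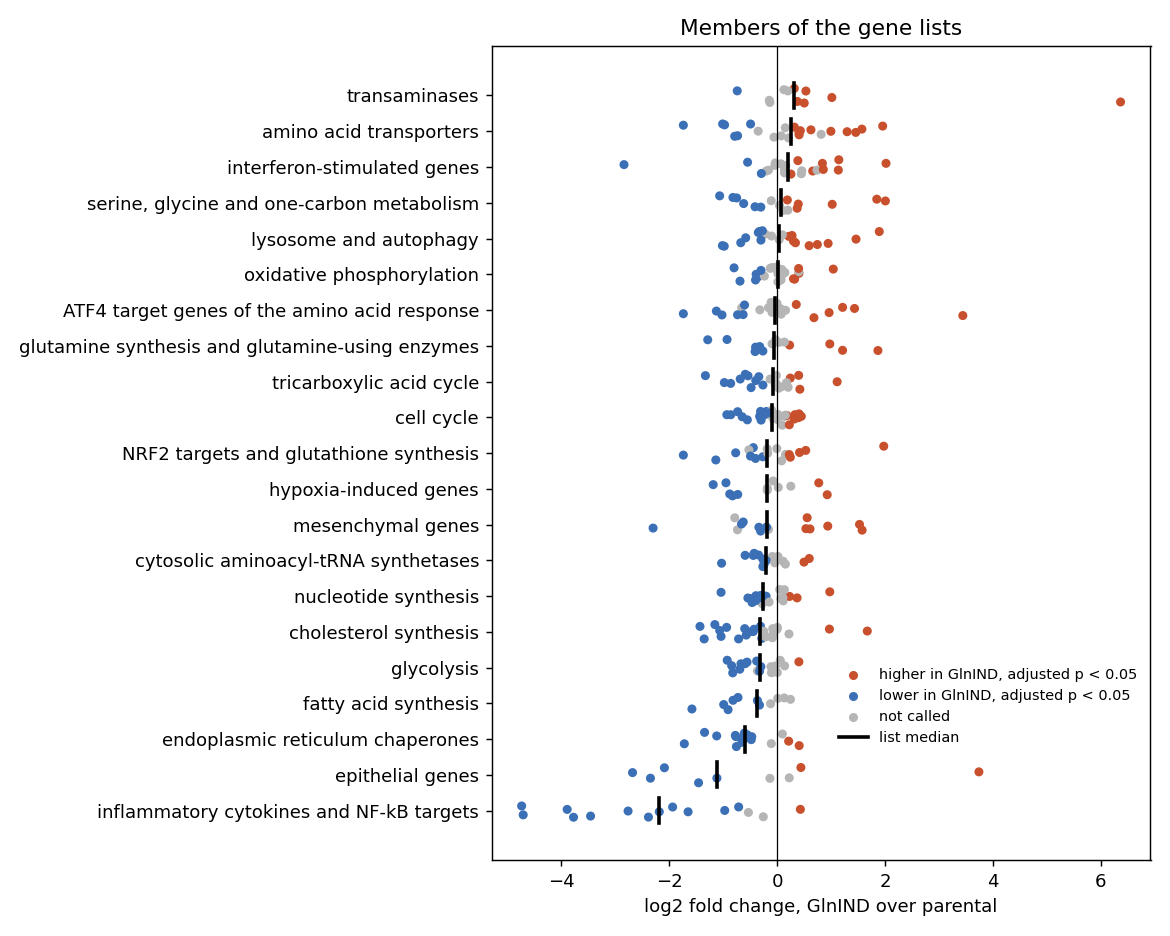
Log2 fold change (GlnIND over parental) of the tested members of the pathway lists, 1 point per gene, coloured by whether the gene was higher, lower or not called at an adjusted p under 0.05, with the list median as a bar. The inflammatory list has its median at -2.18 and the chaperone list at -0.60, while the serine list has members on both sides.

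Summaries of a list could differ in sign. The median and camera direction of the glutamine and ATF4 target lists were negative while their means were 0.05 and 0.06, and oxidative phosphorylation had a median of 0.01 and a mean of -0.02. Camera and fry gave opposite directions for the luminal markers. The medians of the glutamine, ATF4 target, tricarboxylic acid cycle, cell cycle and blood cell lists turned positive with upper-quartile factors or library totals, that of oxidative phosphorylation negative with RLE factors. Leaving out 1 library turned the medians of the serine list (0.077, and -0.015 without parental 2), the ATF4 targets (-0.047, and 0.06 without parental 3), the lysosome list (0.04, and -0.042 without parental 1), the blood cell markers (-0.012, and 0.1 without parental 1) and oxidative phosphorylation (negative without parental 1, parental 2, GlnIND 1 or GlnIND 2). The oxidative phosphorylation and lysosome medians were also negative with DESeq2 and with the GC trend removed, the blood cell median was positive with DESeq2 or no filter, and with no filter or the neighbour shift removed the lysosome median was negative. The mesenchymal median was 0.04 with the neighbour shift removed against -0.195. No list's call at the preset correlation was kept with an estimated correlation, where 0 of 22 lists passed. With fry 15 lists passed.

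Neighbouring genes shifted together along chromosomes. Over 11795 expressed genes in chromosomal order, the correlation of a gene's log2 fold change with that of the next gene was 0.263 across genes, which are not independent replicates, against at most 0.024 in 1000 shuffled orders. In 10 of 297 windows the median lay beyond the most extreme window of every shuffle (0.73 in size), 9 of them lower and 1 higher. This count rested on the limit, which is the largest value of its shuffles. Shuffles without 1 library gave limits of 0.515 to 0.635, with 21, 28 and 23 windows beyond them without parental 1, 2 and 3, and 24, 16 and 24 without GlnIND 1, 2 and 3. At the limit from all libraries the count without 1 library was 8 to 11. On chromosome 11 the 185 genes from ANKRD42 to GLB1L2 had a median of -0.98, and 168 of them were lower. On chromosome X the 126 genes from LONRF3 to TMLHE had a median of -0.96, with 111 lower. The 40 genes from IFRD1 to ATP6V1F on chromosome 7 had a median of -0.74, and the 40 genes from C16orf87 to PLLP on chromosome 16 a median of 0.75, with 39 higher. Stretches of windows short of the 0.73 limit also had medians on 1 side. All windows of chromosome 13 had medians of -0.61 to -0.39. On chromosome 3 the windows from TRNT1 to GNL3 had medians of 0.29 to 0.47, against -0.04 to 0.09 from ADAMTS9 onward. The 10 windows therefore do not mark the full extent of the shifts.

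**Figure D3:**
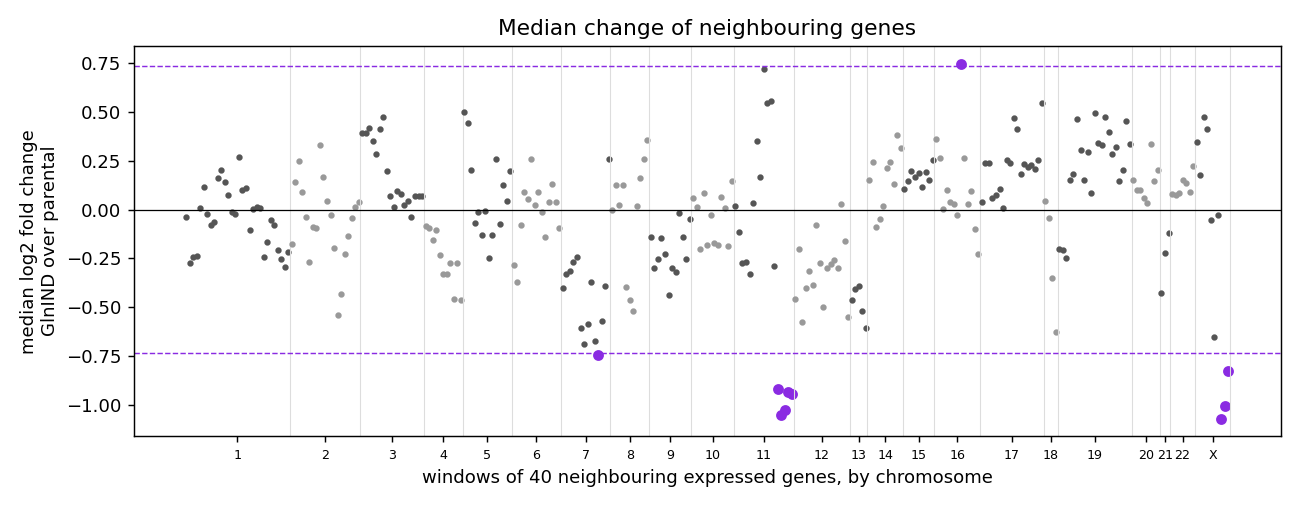
Median log2 fold change (GlnIND over parental) in windows of 40 neighbouring expressed genes, 1 point per window in chromosomal order, with dashed lines at the largest window median of 1000 shuffled orders (0.73 in size). The purple points are the 10 windows beyond the lines, on chromosomes 7, 11, 16 and X. Stretches between the lines also lay on 1 side, such as all windows of chromosome 13 (-0.61 to -0.39). With the lower limits found without 1 library, 16 to 28 windows lay beyond.

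Libraries separated by group and, within the parental group, by 1 library. Pearson correlations of log2 CPM across genes were 0.985 to 0.992 between parental libraries, 0.994 between GlnIND libraries and 0.930 to 0.936 between groups. The chi-square per degree of freedom of count differences was 3.42 to 4.12 between GlnIND libraries, 4.07 between parental 2 and parental 3, and 23.7 and 33.0 between parental 1 and these. Counting both ends of a read pair and PCR copies also raise this value, so whether the closest pairs exceed sampling noise stays open. The first principal component held 83.8% of the variance and split the groups, and the second held 7.8% and set parental 1 apart. Without parental 1, 4601 genes rose and 4679 fell. Across genes, the deviation of parental 1 from the other parental libraries fell with transcript GC content (Spearman's rho -0.518). The median log2 fold change between groups was -0.25 in the lowest GC decile and 0.26 in the highest. Mitochondrial ribosomal RNA (RNR1 and RNR2) took 0.717% to 0.875% of parental and 0.439% to 0.515% of GlnIND counts, and the nuclear transcripts NEAT1 and MALAT1 took 0.0104% to 0.0136% and 0.0664% to 0.0861%.

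**Figure D4:**
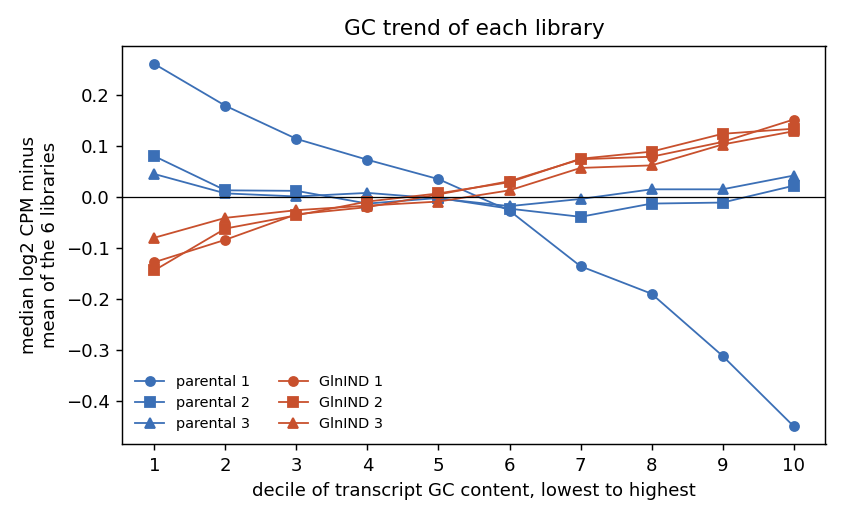
Median deviation of log2 CPM from the mean of the 6 libraries, by decile of transcript GC content, 1 line per library. Parental 1 falls from 0.26 in the lowest decile to -0.45 in the highest, while parental 2 and 3 stay between -0.04 and 0.08. The GlnIND libraries rise, from between -0.14 and -0.08 in the lowest decile to between 0.13 and 0.15 in the highest.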

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

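The removal of the GC trend, the removal of the neighbour shift and the use of library totals alone were chosen after the data had been seen, and the other alternatives before. The count of changed genes stayed within 1.5 times of 7853 in all alternatives except the test against a log2 fold change of 1, which uses a stricter null and gave 1006 genes, 656 higher and 350 lower. Without 1 library the count ranged from 6516 to 9280, with 3151 to 4601 higher and 3337 to 4679 lower. DESeq2 gave 7760 and limma-voom 7939 genes, and the deposited matrix gave the same 7853. With the GC trend removed 8338 genes were called and 7085 were shared in direction with the 7853. With the neighbour shift removed 6715 were called and 5463 were shared.

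The log2 fold change of PSAT1 was positive in all alternatives. It passed the threshold at 0.29 with upper-quartile factors, 0.35 with library totals, 0.27 with the GC trend removed and 0.35 with the neighbour shift removed, and ranged from 0.11 to 0.23 without 1 library, passing only without parental 1, where the value was smaller and its SE fell to 0.051. Its adjusted p over the alternatives that estimate the change ranged from 0.00807 to 0.315. The scaling shift of all genes accounts for the gain under upper-quartile and total scaling. The gain with the neighbour shift removed follows from its construction, since the window that holds PSAT1 had a median of -0.15. The cause of the other gains was not tested.

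The number of lists that shifted was 5, and 3 to 5 without 1 library, with 3 in the fits without parental 2, GlnIND 1 or GlnIND 3. It was 4 with upper-quartile factors, library totals or the neighbour shift removed, 0 with an estimated correlation and 15 with fry, which tests another hypothesis. Inflammatory, chaperone and cholesterol genes lost their call only with the estimated correlation. With the neighbour shift removed GPT2 turned to -0.23 and NDUFA1 to 0.28, by the construction of that alternative, since their neighbours had moved the same way. Of the 58 named genes, 53 kept direction and call there, 56 with the GC trend removed, and 58 with RLE factors, either filter, DESeq2, limma-voom and robust dispersion. In the test against a log2 fold change of 1, 23 of the 58 lost their call and 43 of 50 counts of list members moved by over 1.5 times.

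No pairing of the libraries by replicate number was visible, and the labels do not say what a shared number means. The deviations of same-numbered libraries from their group means correlated at -0.063, 0.030 and -0.037 across genes. With the number as a replicate block 7303 genes were called, 3719 higher and 3584 lower, 5 lists shifted, PSAT1 stood at 0.20 (adjusted p = 0.122), and no named gene or list changed its call. Depth limited genes near 6 counts, whose floor was 0.244 to 0.329 CPM per library.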

Other observations

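The genes and families in this part were chosen after their values were seen, and so were the tests of GC content and depth for parental 1, of GC content for the neighbouring genes and of the CDKN2A region, and the removal of the GC trend and of the neighbour shift. The clustered protocadherin genes PCDHB, neuronal cell adhesion genes in a tandem array on chromosome 5, rose as a family. Of 17 tested members 16 were higher in GlnIND cells and 0 lower, with a median log2 fold change of 2.45 (camera adjusted p = 2.18e-05 over 165 families of genes sharing a symbol stem, adjusted p = 0.992 with an estimated correlation). With an estimated correlation camera gave all 165 families an adjusted p of at least 0.992. That version, with its few degrees of freedom, therefore cannot tell the families apart. PCDHB13 rose from 2.40 ± 0.148 to 13.4 ± 0.774 CPM and PCDHB16 from 2.93 ± 0.214 to 10.4 ± 0.944 CPM (SD, n = 3 each), while PCDHB2 was at 8.93 and 8.68 CPM. These genes are similar in sequence and adjacent, so reads shared between them are uncertain and members are not independent. The family kept a camera adjusted p of 2.53e-05 with the neighbour shift removed. That removal changed little, since the window of PCDHB13, PCDHB16 and PCDHB2 had a median of 0.26, and PCDHB13 went from 2.47 to 2.24. It does not test a local shift narrower than a window. Of 40 ubiquitin-conjugating and related UBE genes 24 fell and 4 rose, with a median of -0.37 (camera adjusted p = 0.0476, adjusted p = 0.992 with an estimated correlation and 0.0292 with the neighbour shift removed). The falls of UBE2A and UBE4A, by 1.06 and 1.03 on the log2 scale, were those of their neighbours, in windows with medians of -1.07 and -1.03, and the genes stood at 0.02 and -0.01 with that shift removed. Of 19 myosin (MYO) genes 11 rose and 1 fell, with a median of 0.38 (camera adjusted p = 0.0476, adjusted p = 0.992 with an estimated correlation and 0.149 with the neighbour shift removed). MYO5C rose from 41.1 to 102 CPM.

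Single genes with large changes lay outside the lists. NEAT1, the long noncoding RNA of nuclear paraspeckles, rose from 90.6 ± 6.30 to 658 ± 88.3 CPM (SD, n = 3 each, edgeR adjusted p = 7.21e-08). CXCR4, a chemokine receptor, rose from 1.06 ± 0.352 to 42.2 ± 2.14 CPM (SD, n = 3 each, edgeR adjusted p = 4.11e-08). CD24, a surface glycoprotein that is low in mesenchymal breast cancer lines, rose from 10.6 ± 0.896 to 31.8 ± 0.644 CPM (SD, n = 3 each, edgeR adjusted p = 1.89e-06). MEST, an imprinted gene, had 2091 counts in parental and 5 in GlnIND libraries, a ratio of 532 (95% interval 151 to 2160). The mitochondrial ribosomal RNA RNR2 fell from 7083 ± 1123 to 3880 ± 237 CPM (SD, n = 3 each, edgeR adjusted p = 0.000103).

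Runs of neighbouring genes shifted together. With the GC trend removed the correlation of adjacent genes was still 0.25 and without parental 1 it was 0.25, both far above the shuffled orders (at most 0.029 and 0.028), which argues against GC content and against that library as the whole cause. In the windows beyond every shuffle the spread of genes about the window median was 0.982 times that of other windows (0.989 to 1.076 times without 1 library), so their genes moved as evenly as those elsewhere. This is consistent with a difference in chromosome copy number between the cultures, a hypothesis that rests on expression alone, and does not separate it from a chromatin change over the same domains. A mix-up with a line that has an intact CDKN2A region finds no support but is not excluded. CDKN2A and CDKN2B had 0 counts in both groups, and MTAP had 0 in parental and 6 in GlnIND libraries (at most 0.263 CPM), but whether reads at these genes were counted in full is not known. The chromatin change was not tested and stays open, and no DNA data were analysed here.

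Parental 1 stood apart from the other parental libraries. Its deviation fell with GC content (rho -0.518), which is consistent with a GC bias of that library, while the decile medians of the other parental libraries stayed between -0.04 and 0.08. Its total of 21741371 counts was the highest of the parental libraries, which argues against low depth. A difference between the cells of that library was not tested. The GlnIND decile medians rose with GC content, from between -0.14 and -0.08 in the lowest decile to between 0.13 and 0.15 in the highest. These medians are relative to the mean of all 6 libraries, so the fall of parental 1 by itself lifts the others with GC content. Parental 2 and 3 share that reference and went from 0.08 to 0.022 and from 0.045 to 0.042 between these deciles. The GlnIND libraries thus rose against them as well, and parental 1 was not the only source of the GC trend between groups.

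For the 5 lists that fell at the preset correlation, 4 kept an adjusted p under 0.05 with the neighbour shift removed and 5 with the GC trend removed, which argues against either as the whole cause. With an estimated correlation 0 of the 5 passed (adjusted p 0.165 to 0.617), so the calls themselves rest on the preset value. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the grouping of the study, gave 7853 genes. The highest of the others with edgeR was 0 (14 to 171 genes at an unadjusted p under 0.05, and 0 with DESeq2 or limma-voom). Every other split mixes parental and GlnIND libraries, so the group difference enters the spread within its groups and few calls follow by construction. The gene count over splits therefore does not test the calls against chance. For the lists 2 splits gave 5, the real one and that of parental 1 with GlnIND 1 and GlnIND 3. Parental 1 with GlnIND 2 and GlnIND 3 gave 4. Every mixed split except parental 1 and parental 2 with GlnIND 1 gave at least 1 list. List calls at the preset correlation thus also arose in groupings that gave 0 genes. For either result 10 splits are too few for a share under 0.05. The effects of glutamine supply, serum type and selection of a derivative stay open, since they changed together.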
